A study of Mus musculus with 4 samples.

How the data were processed

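Tibialis anterior, a fast muscle at the front of the lower leg, was measured in 4 mouse muscles by TOMO-seq. In this assay a tissue is cryosectioned along one axis and the RNA of each section is sequenced under its own barcode. Per the labels' protocols, RNA of single sections was extracted with TRIzol and primed in 96-well plates by CEL-Seq2, a method that counts transcript 3' ends. Per the same protocols, each primer carried a unique molecular identifier (UMI) of 6 bases and a section barcode of 8 bases. The labels do not say that the muscles came from separate animals. The p-values of the zone fits therefore measure only the spread among sums from these samples, which may be technical.

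For each muscle the authors deposited an estimated count per gene and section barcode for 96 barcodes. Reads were aligned with STAR 2.7.7a to GRCm38, per the submitters' processing notes. The counting program, the annotation behind the gene names and the use of strand are not given in the sources used here. The values of these deposited tables are not whole numbers. At least 99.99% of them in every muscle are within 0.001 of a UMI what a whole number of UMIs becomes after correction for UMIs that were drawn more than once out of 4096 possible ones. Where all UMIs of a gene were seen the value is capped at 62356, which happened for 576 values over all barcodes. With 1 UMI unseen the correction would give 34065. For 22 genes at least 90% of the UMIs were used in 1 or more kept sections. Most were mitochondrially encoded, and Atp2a1, Tnnt3, Tpm1, Aldoa, Ckm, Tnnc2, Pvalb, Myl1 and Myh4 were among the others. Differences of these genes are uncertain, and they are called saturated where named.

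The authors also deposited a filtered table per muscle, whose unit is a normalized signal. From the values, it holds the counts of a subset of genes and sections times 1 factor per section, so that all sections of a muscle have the same total (100% of the sections matched within a relative tolerance of 1e-06). These signal values were used only to learn which sections the authors kept. They kept 37, 45, 46 and 43 sections of muscles 1 to 4. Sections were ordered by barcode number and placed at a relative position from 0 (first kept) to 1 (last kept). The labels do not give the order of sectioning or which end of the muscle came first, so "first end" means the low barcode numbers. Muscles 1 and 2 used a different set of section barcodes from muscles 3 and 4, which is treated as a batch.

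Entries that name several genes were left out of tests and library sizes, and held from 0.58% to 0.93% of the counts of a muscle. Gene names were matched by identifier to GENCODE M21 (28895 of 28989), which also gave the GRCm38 coordinates. Each muscle was divided into 5 zones of equal length, and counts were summed per muscle and zone and rounded, which gave 20 sums of 2007511 to 6650590 transcripts. The sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05) with muscle as a block, because zones of 1 muscle share an animal. The contrasts were the mean of zones 1 and 5 minus zone 3 (ends versus middle), zone 1 minus zone 5 (first end versus last end), and any difference among the 5 zones. In all, 9317 genes were tested, with a biological coefficient of variation of 7.03%. Standard errors (SE) of log2 differences were derived from the F statistic. SE and p-values rest on the spread of all 20 sums around zone and muscle effects, with information shared between genes. They do not rest on the spread of the per-muscle differences, which can be wider. For Mss51 at the ends these were 0.76, 0.73, 3.51 and 1.30 in muscles 1 to 4, against an SE of 0.15 for the fitted difference. Within each muscle alone, single sections were fitted with a natural spline of position with 4 degrees of freedom, for genes with a count in at least 25% of the sections. Sections are not animals, so these p-values measure the spread between sections of that muscle.

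The design, the contrasts, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes, per contrast, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with the same sign in all 4 muscles and a mean of at least 10 CPM (counts scaled to a common library total). Clone names and pseudogenes are skipped. It named 35 genes, and members of the lists are named besides; 1 gene is not reported here by name. There were 14 lists of muscle genes (myotendinous junction, tendon, neuromuscular junction, slow fibre, fast fibre, myosin heavy chains, immature or denervated fibre, glycolysis, fatty acid oxidation, nuclear oxidative phosphorylation with some other mitochondrial enzymes, mitochondrially encoded, extracellular matrix, limb patterning, immediate early and stress). A further 10 lists held markers of other cells (fibro-adipogenic progenitor, endothelial, smooth muscle and pericyte, satellite cell, Schwann cell, macrophage, adipocyte, erythrocyte, skin, cartilage and bone). Of these 24, the 21 with at least 3 measured members were tested with limma 3.58.1 camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over all lists of a contrast. camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. Myosin composition and the position of junction transcripts were summarised as mean and SD over 4 muscles without a test, since 4 pairs are too few for an exact sign-flip test to reach p = 0.05.

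Simulated counts with 200 changed genes were put through the same zone fit of 9317 genes. For ends versus middle it recovered 59% of changes of 1.5-fold and 83% of 2-fold, with 6.58% of the calls false. For first end versus last end it recovered 37% and 64%, with 2.88% false. Within single muscles, changes of 4-fold were recovered for 32.3%, 37.2%, 52.6% and 39.4% of the genes in muscles 1 to 4, and in muscle 3 13.4% of the calls were false. A list of 15 genes raised 1.4-fold was simulated in 1 draw, for ends versus middle only, and was called. This gives no recovery rate for lists.

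The alternatives were DESeq2 1.42.0 as size factors and as a test, no low-count filter, 3 or 10 zones, no replicate block, sections chosen by a threshold of 20% of the median total over all barcodes, no mitochondrial transcripts, sections weighted equally in limma on log2(mean CPM + 1), and each muscle left out in turn. Chosen after seeing the data were a threshold of 20% of the median kept section, the outermost sections left out (positions under 0.05 or over 0.95), UMI numbers without the correction, saturated genes left out, entries naming several genes kept, each barcode set alone, and zone sums thinned to the shallowest (1989683 transcripts). Confidence intervals of shares are exact binomial at 95% and cover counting error only, as do limits set by a count of 0 (3 counts). Tables were prepared and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.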

Results

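The data were 171 kept cross-sections along 4 mouse tibialis anterior muscles, all of 1 group, and the design asks which transcripts vary with position along the muscle. The kept sections held 19102441, 17256419, 27174920 and 23011841 transcripts in muscles 1 to 4. Single sections ranged from 86744 to 1171405 transcripts. The median section showed 10517, 9250, 10384.5 and 9438 genes in the 4 muscles. Mitochondrially encoded genes took 58.6%, 60.4%, 63.7% and 66.5% of the corrected transcripts. Most of the saturated genes are among them, so these shares are uncertain. Zones 1 to 5 run from the first to the last kept section, and all log2 differences below are between zone sums of the same muscle.

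Ankrd1 and Mss51 were higher at the ends of the muscle than in its middle, and Chrne, Etv5 and Myh2 were lower. Ankrd1, a titin-binding protein induced by stretch, was 2.24 ± 0.28 log2 units (SE) higher at the ends, with 13.4 ± 8.14 CPM (SD, n = 4) in zone 1 and 2.24 ± 1.18 in zone 3 (edgeR adjusted p = 2.41e-07). Chrne, the adult epsilon subunit of the acetylcholine receptor at the synapse, was lower at the ends (log2 difference -1.01 ± 0.21, edgeR adjusted p = 0.00311), as was Etv5, a transcription factor of synaptic nuclei (-1.70 ± 0.37, edgeR adjusted p = 0.00436). Both kept that direction wherever tested, but neither was called with the outermost sections left out, nor Chrne without muscle 3 or Etv5 with 3 zones. Myh2, the myosin heavy chain of fast oxidative type 2A fibres, was lower at the ends in 4 of 4 muscles (-0.71 ± 0.09, edgeR adjusted p = 6.17e-07). Mss51, a mitochondrial protein enriched in muscle, was the gene with the largest rise at the ends among those the naming rule took (1.17 ± 0.15, edgeR adjusted p = 3.08e-07), with 0.76, 0.73, 3.51 and 1.30 in muscles 1 to 4.

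Of the genes that met the naming rule, 39 were higher at the ends and 39 lower. The other 9 of the 10 largest rises were Net1, an activator of the small GTPase RhoA (0.91), Tmem100, a transmembrane protein (0.80), Ctxn3 (0.71), Svbp (0.63), Wsb2 (0.62), Zfp943 (0.57), the ectodysplasin receptor Eda2r (0.55), the joint lubricant Prg4 (0.55) and Serinc2 (0.54). The 10 largest falls were the slow myosin light chain Myl3 (-0.92 ± 0.13), the chemokine Cxcl14 (-0.87 ± 0.11), the Z-disc protein Myoz2 (-0.81), the mitochondrial transfer RNA mt-Tm (-0.74), Myh2, the basement membrane collagen Col15a1 (-0.64), the actin nucleator Lmod2 (-0.63), Otud1 (-0.61), the stretch-induced protein Ankrd2 (-0.60) and the microfibril protein Mfap5 (-0.59). In this set the edgeR adjusted p ran from 2.41e-07 for Cxcl14 to 0.0331 for Prg4. Prg4 was higher at the last end alone, at -0.51 in zone 1 and 1.61 in zone 5 relative to zone 3. Mss51 lies on chromosome 14 at 20482867 to 20496901 (GRCm38), Ankrd1 on chromosome 19 at 36111961 to 36120099 and Myh2 on chromosome 11 at 67171027 to 67197517. Chrne, Prg4, Myl3, Wsb2, Ctxn3, Col15a1 and Myh2 overlap a gene on the opposite strand, as do Casq1, Mybpc2, Tpi1, Pgm1, Myl4 and Jun below, and since the use of strand is not given, their counts can include its transcripts.

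**Figure D1:**
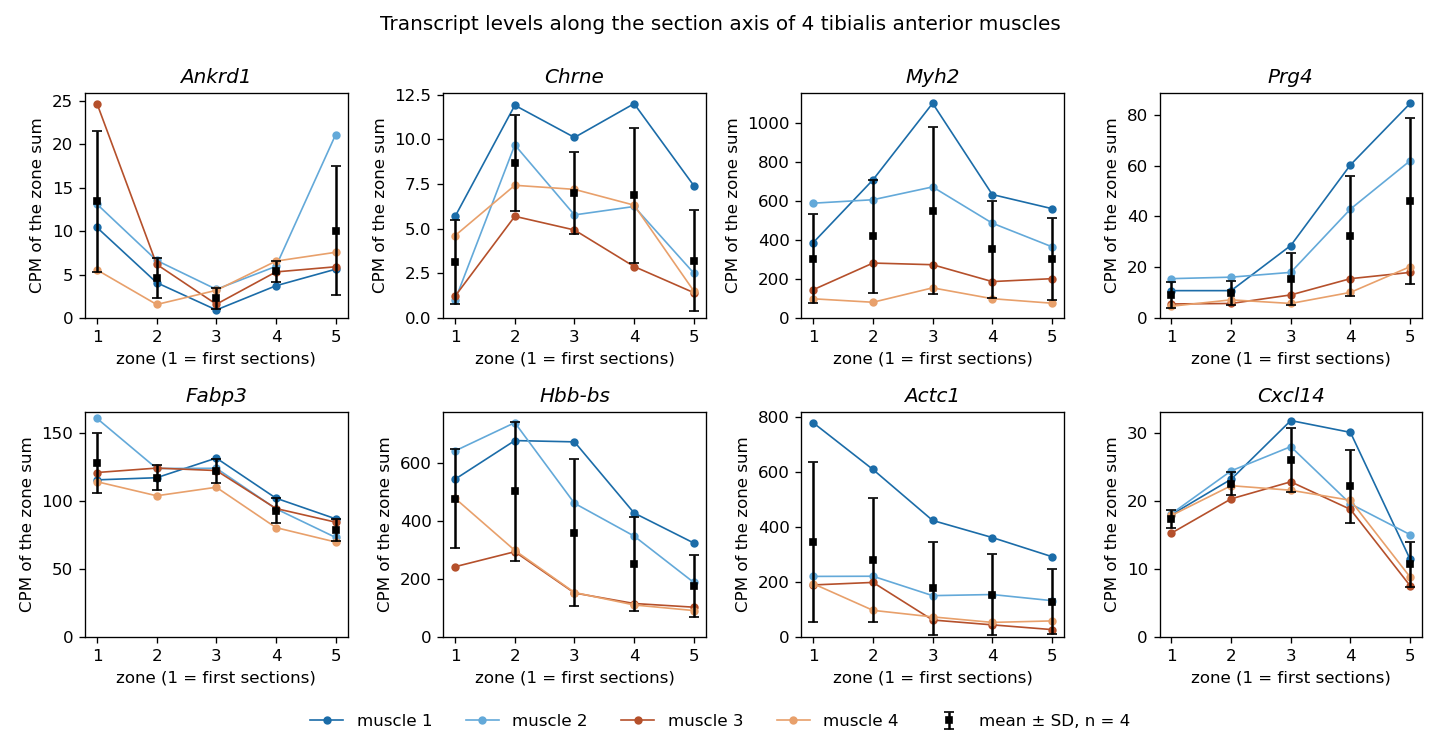
Expression in CPM (vertical axis) across the 5 zones from the first to the last end (horizontal axis) for 8 genes; thin lines are the 4 muscles and points with bars the mean and SD over them. Mean Ankrd1 was 13.4 and 2.24 CPM in zones 1 and 3, mean Chrne 3.13, 8.68 and 3.21 in zones 1, 2 and 5, and mean Prg4 9.08 and 46.1 in zones 1 and 5.

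Among the lists of muscle genes, those of fast fibres and glycolysis were higher at the ends, with 3 of 12 genes called in each. Both passed by camera with the preset correlation and by fry (fry adjusted p = 0.00721 and 0.00294), but not by camera with an estimated correlation. Of 12 fast fibre genes 3 rose (6 adjusted over the list alone): the calcium buffer Casq1 (0.38), myosin-binding protein Mybpc2 (0.27) and the saturated light chain Myl1 (0.26). The list as a whole was higher (camera adjusted p = 2.91e-06, and 0.106 with an estimated correlation). Of its 12 measured genes 6 are saturated, and with saturated genes left out the camera adjusted p was 0.00148 (0.108 with an estimated correlation). Of 12 glycolysis genes Tpi1 (0.22), Pgm1 (0.27) and Pkm (0.28) rose, 8 did when adjusted over the list alone, and the camera adjusted p was 7.42e-06 (adjusted p = 0.106 with an estimated correlation). Of 9 myotendinous junction genes only Ankrd1 rose (2 adjusted over the list alone; camera adjusted p = 0.0227; adjusted p = 0.106 with an estimated correlation). Col22a1, the collagen specific to that junction, had a difference of 0.81 ± 0.33 that did not pass (edgeR adjusted p = 0.268). Of 5 tendon genes Prg4 and the matrix protein Chad (1.01) rose, 2 also adjusted over the list alone (camera adjusted p = 0.00174; adjusted p = 0.106 with an estimated correlation). Chad too was higher at the last end alone, at -0.28 in zone 1 and 2.30 in zone 5 relative to zone 3, and Fmod, not called, was at -0.74 and 1.94. Of 5 genes of immature or denervated fibres the embryonic light chain Myl4 rose (1.80 ± 0.37) and 3 did adjusted over the list alone (camera adjusted p = 0.0481; adjusted p = 0.106 with an estimated correlation).

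Of 11 neuromuscular junction genes, Etv5 and Chrne fell, while 3 fell and Chrnb1 rose adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.106 with an estimated correlation). Of 4 slow fibre genes Myl3 fell, also adjusted over the list alone (camera adjusted p = 0.0493, and 0.147 with an estimated correlation). With zone sums thinned to the shallowest the slow fibre list did not pass (camera adjusted p = 0.0519). Of 14 fatty acid oxidation genes the lipoprotein lipase Lpl fell (-0.35; relative to zone 3 it was at 0.068 in zone 1 and -0.77 in zone 5) and 5 fell adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.312 with an estimated correlation). Of 20 nuclear genes listed under oxidative phosphorylation Cox8b (-0.39) and Ndufa4 (-0.46) fell, 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0570). Of 6 immediate early genes Jun fell (-0.27; 1 adjusted over the list alone; camera adjusted p = 0.0493; adjusted p = 0.106 with an estimated correlation). The remaining lists did not pass by camera: myosin heavy chains (3 measured, adjusted p = 0.235), mitochondrially encoded (13, adjusted p = 0.384, median 0.07 with a mean of -0.00), extracellular matrix (14, adjusted p = 0.118) and limb patterning (6, adjusted p = 0.343). Within them Myh2, mt-Atp8 (-0.39) and Col6a2 (-0.48) fell and no limb patterning gene was called by edgeR. Adjusted over the list alone, 1 rose and 2 fell among the myosins, 1 and 1 among the mitochondrial genes, 1 and 2 in the matrix list, and 1 and 0 among limb patterning genes.

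Of the lists of cells between the fibres, those of fibro-adipogenic progenitors and macrophages were lower at the ends with both correlations. Of 9 markers of fibro-adipogenic progenitors, the connective tissue cells of muscle, Dcn (-0.41), Cxcl14, Gsn (-0.33, lower in 2 of 4 muscles) and Mfap5 fell, and all 9 fell adjusted over the list alone. That list passed by camera with the preset (adjusted p = 2.05e-12) and the estimated correlation (adjusted p = 0.00309). Of 5 macrophage markers C1qb fell (-0.60) and 5 did adjusted over the list alone (camera adjusted p = 7.41e-05, and 0.0370 with the estimated correlation). With zone sums thinned to the shallowest, camera with the estimated correlation no longer called the macrophage list (adjusted p = 0.123). Of 6 Schwann cell markers 4 fell, among them the myelin genes Pmp22 (-0.65) and Mbp (-1.04) and the regulator Sox10 (-0.93), and 4 did adjusted over the list alone (camera adjusted p = 3.81e-04; adjusted p = 0.106 with an estimated correlation). Of 10 endothelial markers Flt1 fell (-0.30), and 2 did adjusted over the list alone (camera adjusted p = 0.0481, and 0.109 with an estimated correlation). With zone sums thinned to the shallowest the endothelial list did not pass (camera adjusted p = 0.100). The fat cell markers Adipoq (1.94 ± 0.43) and Cfd (1.60 ± 0.40) rose, both also adjusted over the list alone, and a list of 2 was not tested. For Cfd, ends versus middle rested on muscle 2: the difference was 0.029 without muscle 2 and -0.021 with zone sums thinned to the shallowest. By camera no difference passed for smooth muscle and pericyte (8 measured, adjusted p = 0.299), satellite cell (3, adjusted p = 0.937, with a median of 0.03 but a negative test direction) and erythrocyte markers (5, adjusted p = 0.846), none of whose members was called by edgeR. No skin marker and 1 of the cartilage and bone markers (Sox9, -0.43, not called) were measured.

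In all, 135 genes differed between ends and middle by edgeR (58 higher, 77 lower; 1105 at unadjusted p under 0.05). Within the barcode set of muscles 1 and 2 the count was 44 and within that of muscles 3 and 4 it was 55. Without muscle 2 it was 74 and without muscle 3 it was 38, and 13, 17, 23 and 2 of the calls of 46 named genes were lost without muscles 1 to 4. Across 1455 genes with a mean of at least 30 CPM, Pearson's r between the differences of 2 muscles ran from 0.0862 (muscles 1 and 4) to 0.412 over the 6 pairs. The balance of directions was 19 higher and 69 lower with equal section weights in limma and 65 higher and 30 lower with DESeq2, which gave no adjusted p for 7045 of the 9317 genes. camera called 13 of 21 lists, 6 without muscle 2 and 8 without muscle 3, and 2 with an estimated correlation. With zone labels reshuffled within each muscle it still called a median of 2 lists in either contrast, so lists near the threshold are uncertain. By fry 12 passed. These lacked the slow fibre (fry adjusted p = 0.0553) and fatty acid oxidation lists (fry adjusted p = 0.0828) and included the myosin heavy chains, which were lower (fry adjusted p = 0.0285). When sections were chosen by a threshold over all barcodes, which takes in barcodes outside the tissue the authors kept, 23 of the 46 named genes changed direction.

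**Figure D2:**
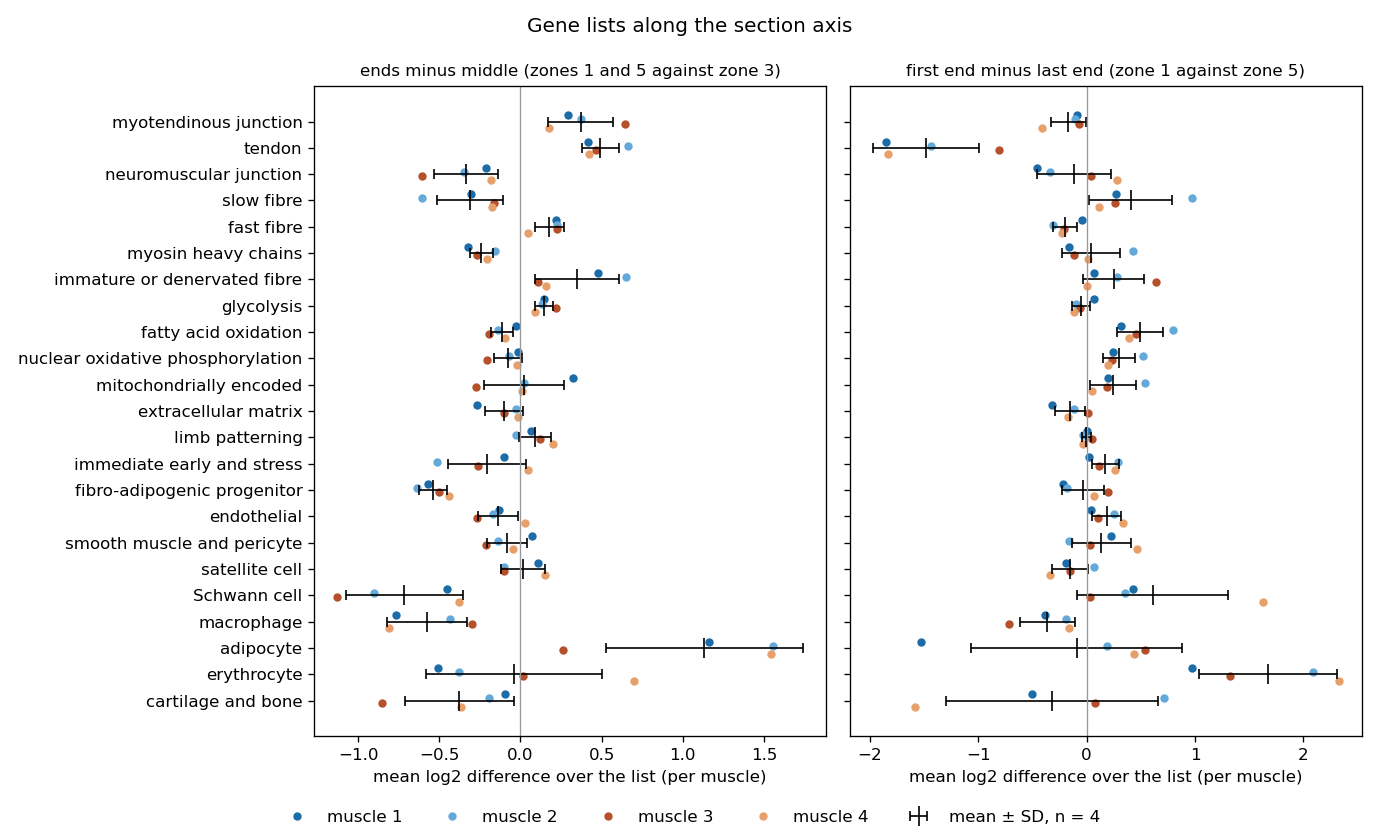
Mean log2 difference of the measured genes of each list (horizontal axis) for ends minus middle and for first end minus last end; small points are the 4 muscles and large points with bars the mean and SD over them. For ends minus middle the fibro-adipogenic progenitor list lay below 0 in all 4 muscles (mean -0.54 ± 0.09), and for first minus last end the oxidative phosphorylation list lay above 0 in all 4 (0.30 ± 0.15).

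Between the 2 ends of the muscle, transcripts of oxidative metabolism and of blood were higher at the first end, and those of tendon at the last. Of 20 nuclear genes listed under oxidative phosphorylation, which include some other mitochondrial enzymes such as Idh2, 14 rose at the first end (19 adjusted over the list alone) and all 20 had a positive difference. Of 14 fatty acid oxidation genes 10 rose (13 adjusted over the list alone). Haemoglobin transcripts were 1.59 to 1.74 log2 units higher at the first end, and Actc1, the cardiac alpha actin also made by immature fibres, was 1.74 ± 0.14 higher. Prg4 (-2.12 ± 0.16), Chad (-2.59 ± 0.25) and the collagen-binding protein Fmod (-2.68 ± 0.28) were lower at the first end in 4 of 4 muscles.

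The oxidative list had a median difference of 0.29 (camera adjusted p = 7.76e-14, and 0.0483 with the estimated correlation). Its largest differences were the matrix enzyme Idh2 (0.78) and, among genes of oxidative phosphorylation itself, Ndufb8 (0.38), Cox4i1 (0.37) and Sdhb (0.35). The fatty acid list had a median of 0.49 (camera adjusted p = 1.36e-16, and 0.0132 with the estimated correlation). It was led by Lpl (0.84), the fatty acid carrier Fabp3 (0.80 ± 0.09), the transporter Cd36 (0.63) and Acadvl (0.60). Of 13 mitochondrially encoded genes mt-Atp8 (0.32) and the saturated mt-Nd3 (0.34) rose, 6 adjusted over the list alone (camera adjusted p = 1.57e-04; adjusted p = 0.190 with an estimated correlation). With 11 of its 13 members saturated, this list could not be tested without them. Of 4 slow fibre genes the calcium buffer Casq2 (0.73) and Tpm3 (0.72) rose, 2 also adjusted over the list alone (camera adjusted p = 0.0225, and 0.133 with an estimated correlation). With zone sums thinned to the shallowest the slow fibre list did not pass (camera adjusted p = 0.0511). Of 12 fast fibre genes Actn3 (-0.37) and the saturated Myh4 (-0.31), the type 2B myosin, fell, 7 adjusted over the list alone (camera adjusted p = 7.12e-05, and 0.190 with an estimated correlation). With saturated genes left out the camera adjusted p of the fast fibre list was 0.00161.

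Of the genes that met the naming rule, 143 were higher and 71 lower at the first end. The largest rises were Hbb-bt (1.74 ± 0.13), Actc1, Hbb-bs (1.68), Hba-a1 (1.63), Hba-a2 (1.59), the heart-type lactate dehydrogenase subunit Ldhb (1.05), the RNA-binding protein Ybx2 (0.96), Cxcl14 (0.89), Lpl and Fabp3. The largest falls were Prg4, Tmem100 (-0.90), Net1 (-0.84), the noncoding RNA Mir99ahg (-0.79), the matrix protein Prelp (-0.73), the Z-disc adaptor Sorbs2 (-0.68), Mustn1 (-0.68), Mss51 (-0.68), the transcription factor Trp63 (-0.68) and the ubiquitin ligase Mib1 (-0.67). Their edgeR adjusted p ran from 1.16e-15 for Hbb-bt to 0.0280 for Trp63. Prg4 lies on chromosome 1 at 150449412 to 150466165 (GRCm38), Fabp3 on chromosome 4 at 130308595 to 130315463, Actc1 on chromosome 2 at 114047282 to 114053548 and Hbb-bs on chromosome 7 at 103826534 to 103828096. The haemoglobin pairs are near-identical copies whose reads the counting could divide, and Fabp3, Actc1, Chad, Mir99ahg, Prelp, Sorbs2, Mib1, Acadvl and Cox4i1 overlap genes on the opposite strand, so these counts are uncertain. Fabp3 was 1.53 units higher in muscle 2 against 0.59, 0.56 and 0.61 in muscles 1, 3 and 4.

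All 5 erythrocyte markers rose at the first end, also adjusted over the list alone (camera adjusted p = 9.39e-14, and 0.0186 with the estimated correlation), alongside the oxidative lists. The 5 tendon genes had a median of -2.12, with 3 lower and 4 lower adjusted over the list alone (camera adjusted p = 2.64e-08, and 0.0132 with the estimated correlation). Of 6 Schwann cell markers 2 rose, among them Sox10 (1.57; 2 adjusted over the list alone; camera adjusted p = 0.0388; adjusted p = 0.288 with an estimated correlation), and the list mean rested largely on muscle 4 (0.43, 0.35, 0.028 and 1.63 in muscles 1 to 4). Of 10 endothelial markers the receptor Kdr rose (0.78; 1 adjusted over the list alone; camera adjusted p = 0.0287; adjusted p = 0.133 with an estimated correlation). Among 8 smooth muscle and pericyte markers Myh11 (0.77) and Acta2 (0.58; -0.17 with 10 zones) rose, 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.49995). In the matrix list Col1a1 (-0.67) and Col1a2 (-0.47) fell, in 3 of 4 muscles each, 2 adjusted over the list alone (camera adjusted p = 0.118). The remaining lists did not pass by camera: myotendinous junction (adjusted p = 0.0848; 1 higher and 1 lower adjusted over the list alone), neuromuscular junction (adjusted p = 0.188), immature or denervated fibre (adjusted p = 0.562; Actc1 rose, the median was -0.20 and the mean 0.20) and glycolysis (adjusted p = 0.314). Nor did myosin heavy chains (camera adjusted p = 0.929, with Myh1 0.29 higher and Myh4 lower), limb patterning (adjusted p = 0.929, median -0.00 and mean 0.01), immediate early genes (adjusted p = 0.666), fibro-adipogenic progenitors (adjusted p = 0.831; Cxcl14 rose, and 2 rose and 1 fell adjusted over the list alone), satellite cells (adjusted p = 0.318) and macrophages (adjusted p = 0.0848; 1 lower adjusted over the list alone). Adipoq (-0.32), Cfd (-0.15) and Sox9 (-0.27) were not called.

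In all, 296 genes differed between first and last end by edgeR (190 higher, 106 lower; 1257 at unadjusted p under 0.05), with 161 within the barcode set of muscles 1 and 2 and 74 within that of muscles 3 and 4. The count was 87 without muscle 2, 180 without muscle 3 and 195 without muscle 4, and of 58 named calls 10, 28, 9 and 12 were lost without muscles 1 to 4. Equal section weights in limma gave 29 higher and 138 lower with a median shift of -0.12 over all genes, and DESeq2, with no adjusted p for 6503 genes, gave 162 higher and 63 lower. With sections chosen by a threshold over all barcodes, which moved the median of all genes to 0.61 here and to -0.31 for ends versus middle, 7 of the 58 named genes changed direction. The contrast takes the 4 muscles as sectioned from the same end. Across the same 1455 genes, Pearson's r between the differences of 2 muscles ran from 0.385 to 0.533 over the 6 pairs, all above 0, and genes are not independent replicates.

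Some difference among the 5 zones was called for 371 genes (edgeR, 1447 at unadjusted p under 0.05), 179 and 158 within the barcode sets. The highest mean CPM over the 4 muscles was in zone 5 for 128 of them, in zone 1 for 96 and in zone 2 for 67. It was in zone 3 for 59 and in zone 4 for 21, and the lowest mean was in zone 5 for 181. Without muscle 2 the test called 199 genes and without muscle 3 it called 173. Of the 135 genes of ends versus middle and the 296 of first versus last end, 25 were shared. Within single muscles, section by section, 153, 356, 420 and 160 genes varied with position in muscles 1 to 4, and with the order of sections permuted 5 times per muscle 0 to 26 did. The 4 lists had 49 genes in common, and 44 of the 49 were among the 371, which were called from the same counts. Independent lists would share 0.00251 of 10471, a figure that takes no account of gene level. Being in all 4 lists does not require the same direction or shape. With total count scaling the 4 lists shared 26. The 49 include Ankrd1, Chrne, Myh2, Actc1, Fabp3, Lpl, Prg4, Chad, Mss51, Net1, Tmem100, Dcn and the globins.

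Type 2B myosin dominated the muscle, and type 2A myosin was on average highest in its middle. Of the transcripts of the adult heavy chains, Myh4 took 83.6% ± 8.94 (SD, n = 4), Myh1 of type 2X fibres 11.3% ± 5.42 and Myh2 5.08% ± 3.53. The 2 barcode sets differed, with Myh4 at 76.1% and 75.7% in muscles 1 and 2 and 90.6% and 92.03% in muscles 3 and 4, and Myh2 at 8.05%, 8.18%, 2.59% and 1.52%. Myh7 of slow fibres was at 0.00161% ± 0.00174, and none was counted in muscle 2, which allows a share of up to 0.00252%. The Myh2 share was 6.96% ± 4.67 in zone 3, 4.84% ± 4.33 in zone 1 and 3.36% ± 2.32 in zone 5, while in muscle 2 it was 10.7% in zone 1 and 10.4% in zone 3. Ends minus middle, it differed by -2.86 ± 2.02 percentage points (SD, n = 4) and was lower in 4 of 4 muscles, and Myh4 differed by 4.71 ± 2.30 points and was higher in 4 of 4. First minus last end, Myh1 differed by 4.22 ± 5.36 points and Myh4 by -5.69 ± 8.84, spreads set by muscle 2, without which the means were 1.54 and -1.28. Myh4 is saturated in 1 section, and Myh1, Myh2 and Myh7 overlap genes on the opposite strand, so their shares are uncertain.

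**Figure D3:**
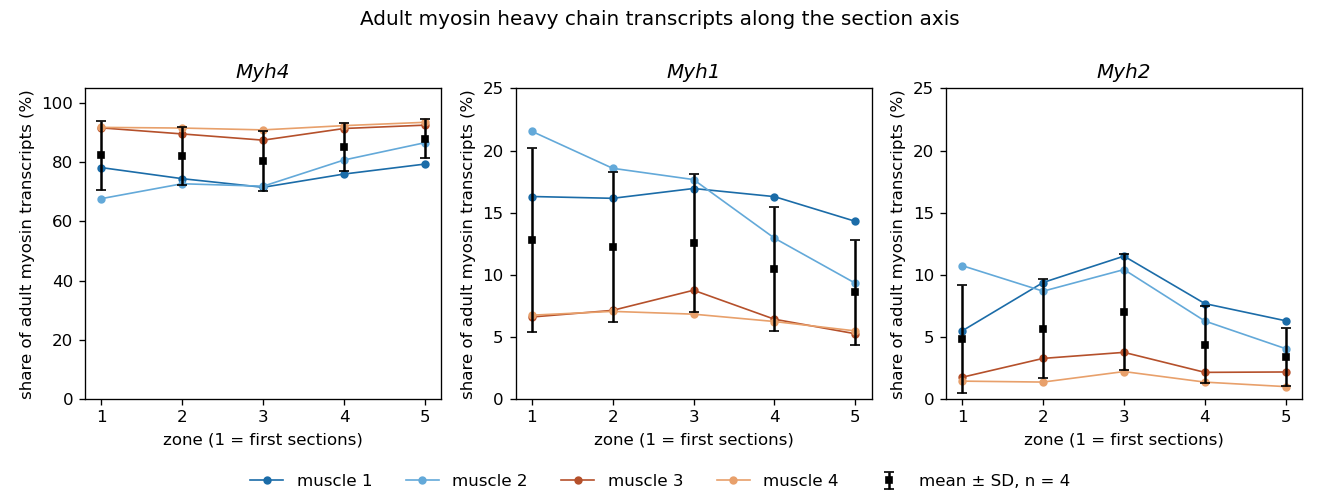
Share of Myh4, Myh1 and Myh2 among the adult myosin heavy chain transcripts in percent (vertical axis) across the 5 zones (horizontal axis); lines are the 4 muscles and points with bars the mean and SD over them. The mean Myh2 share was 6.96% in zone 3 against 4.84% in zone 1 and 3.36% in zone 5.

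Transcripts of the synapse lay around the centre of the muscle, and Col22a1 lay on average farther from it. The summed CPM of 6 synaptic genes (Chrne, Chrna1, Chrnd, Colq, Musk, Ache) had a mean position of 0.502 ± 0.029 (SD, n = 4), with 27.1%, 23.4% and 22.3% of the signal in zones 2, 3 and 4 and 15.7% in zone 5. In muscle 1 zone 3 held 17.4%, less than the 21.9% in zone 5. Their mean distance from the centre was 0.211 ± 0.015, where an even spread over the kept sections would give 0.259, and it was below that value in 4 of 4 muscles (0.197 to 0.233). Col22a1 had a mean position of 0.542 ± 0.113 and a mean distance of 0.304 ± 0.038 (0.272 to 0.347), with 24.1% ± 16.9 in zone 1 and 32.6% ± 7.01 in zone 5. In zones 1 and 3 it had 13.7% and 14.4% in muscle 1 and 6.39% and 18.2% in muscle 4. With counts in place of CPM as weights its distance was 0.265, close to the 0.259 of an even spread. The distance from the centre was chosen after seeing the data, no test was made, and Col22a1 averaged 2.90 CPM. Chrne, Ache and Col22a1 overlap genes on the opposite strand.

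Barcodes more than 5 positions outside the kept range held few transcripts, with medians of 0.529% to 1.05% of the median kept section. In the 25 barcodes after the last kept section, tendon genes stood at 5372, 1370, 4120 and 1083 CPM of nuclear genes (mitochondrially encoded genes left out of the total) in muscles 1 to 4, against 295, 178, 174 and 169 in the kept sections. Before the first kept section they were at 288, 264, 422 and 98.2 CPM. Adipocyte genes after the last kept section were at 133, 1122, 240 and 767 CPM, against 15.1, 27.5, 8.77 and 5.95 in the kept sections. Fast fibre genes were at 264650, 238994, 235554 and 276652 CPM there, against 244972, 235976, 247546 and 284894.

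**Figure D4:**
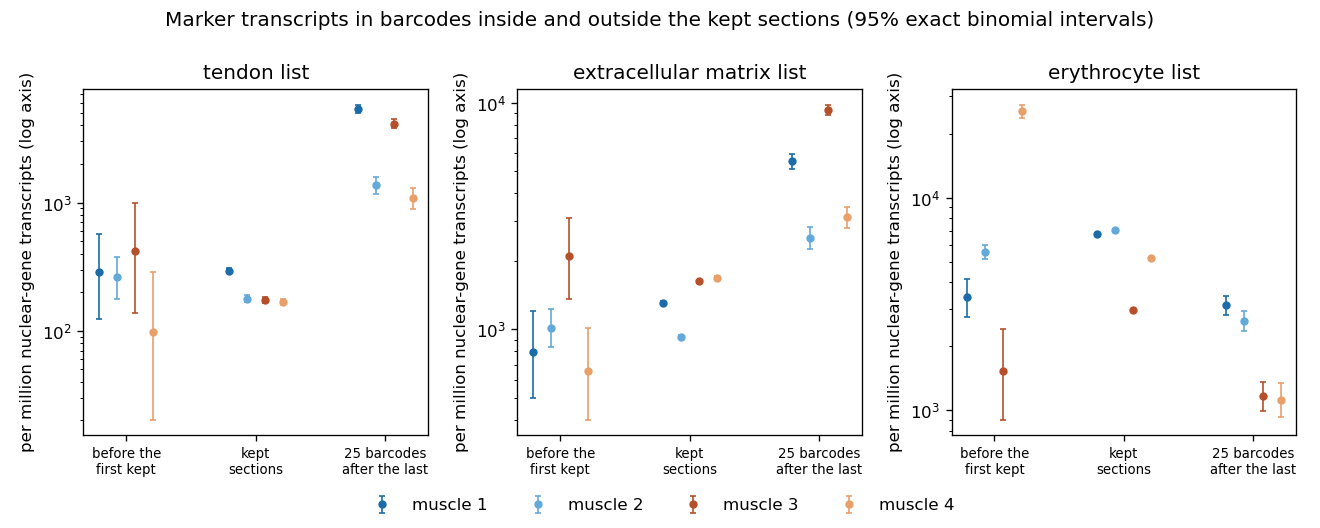
Level of the tendon, extracellular matrix and erythrocyte lists in CPM of nuclear genes (vertical log axis) before the first kept section, in the kept sections and in the 25 barcodes after the last one, for the 4 muscles; bars are 95% exact binomial intervals, which cover counting error only. Tendon genes stood at 1083 to 5372 CPM after the last kept section and at 169 to 295 in the kept sections.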

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

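The counts of genes with reshuffled zone labels, the tests of RNA from other cells, and the tests of the tendon and muscle pair patterns were chosen after the result was seen, and the depth and few-genes settings were added after seeing the data, with what they should show written before their own results.

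With zone labels reshuffled within each muscle (100 splits, the real one included), the real labels called more genes than any other split. This argues against chance, although 100 splits can give no share below 1 of 100 and take the zones of a muscle as exchangeable. The real split alone reached its count for ends versus middle (1 of 100; 135 genes, highest other 45), for first versus last end (1 of 100; 296, highest other 30) and for any zone (1 of 100; 371, highest other 44). The lists called at the ends also outnumbered those of any other split (1 of 100 splits, with 13 lists, highest other 11). For first versus last end 4 of 100 splits gave as many lists (9, highest other 10). The reshuffled splits had a median of 2 lists in each contrast, so camera with the preset correlation also called lists without the real zone order. Lists near the threshold are therefore uncertain.

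Oxidative transcripts were higher at the first end. The tests argue against total depth and a few abundant genes as the cause but leave RNA of other cell types open. With zone sums thinned to an equal total the nuclear oxidative phosphorylation list stayed higher (camera adjusted p = 1.32e-12, median 0.27). It did so too with mitochondrial and saturated genes left out (camera adjusted p = 5.25e-14, median 0.30). The depth of nuclear genes was not made equal, as the mean mitochondrial share per zone ran from 55.6% to 71.1%. A lower share of fibre RNA with all other cell types raised alike would raise their markers by like amounts. The endothelial list exceeded the macrophage list, which did not pass (camera adjusted p = 0.0848), by 0.547 ± 0.185 log2 units (SD, n = 4, lowest 0.422). This argues against that even form only, since a lower fibre share with other cells unevenly placed would also give unequal lists. More RNA of cell types with some markers higher at the first end cannot be told apart from a change within fibres. These were endothelial (1 of 10 called, camera adjusted p = 0.0287, and 0.133 with an estimated correlation), Schwann (2 of 6, camera adjusted p = 0.0388, and 0.288 with an estimated correlation) and red blood cells (5 of 5). The oxidative list exceeded the endothelial list by 0.114 ± 0.178 (lowest -0.139). Its mean of 0.30 ± 0.15 lay below those of the Schwann cell (0.61 ± 0.70) and erythrocyte lists (1.68 ± 0.64). In muscles 1 to 4 the oxidative list was at 0.241, 0.519, 0.233 and 0.201. The erythrocyte list was at 0.969, 2.09, 1.32 and 2.33, and the Schwann cell list at 0.429, 0.351, 0.028 and 1.63. A gradient of fibre metabolism may remain as a hypothesis beside RNA of other cell types, and which anatomical end came first is not known.

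Tendon transcripts stood out in barcodes outside the sections the authors kept, which entered no main comparison. In the 25 barcodes after the last kept section they stood at 5372, 1370, 4120 and 1083 CPM of nuclear genes in muscles 1 to 4. These shares were 6.41 to 23.7 times those of the kept sections. Background from the pooled library would carry the kept sections' own mixture, so the values argue against it as the source of the tendon excess alone. Extracellular matrix genes were 1.85 to 5.69 times higher there, while fast fibre genes were at 0.952 to 1.08 times. Background would also give such a fast fibre share, so it can hold part of the other RNA in these barcodes. RNA of tendon or other connective tissue beyond the kept sections is therefore a candidate source, as a hypothesis found and tested on the same data.

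Muscles 1 and 2 differed from muscles 3 and 4 in sex-linked transcripts and in many others. Xist was counted 868, 751, 1 and 0 times in muscles 1 to 4, and 4 Y-linked genes 20, 19, 2464 and 1339 times, a level at least 52.7 times higher in muscles 3 and 4, which argues against the barcode set alone, since barcodes do not tell sex-linked genes from others. A sex difference is a candidate explanation of that part, although the labels do not state the sex. By edgeR 3538 of 13240 genes differed between the pairs (5218 at unadjusted p under 0.05; no other tool was run). For these genes a library batch and a difference that goes with the sex-linked transcripts cannot be told apart, because the same muscles share both, and for part of them a difference in counting or annotation stays open too (Rps13 was counted 8, 8, 3153 and 2882 times and its near-identical copy Rps13-ps1 606, 512, 1 and 0 times).

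Muscle 2 lay far from the other 3 muscles in 4 quantities of the first versus last end comparison: its Myh1 share differed by 12.2 points, its Myh2 share by 6.69 points, its Myh4 share by -18.9 points, and its Fabp3 level by 1.53 log2 units. Muscle 4 lay apart in the erythrocyte list before the first kept section, with 25561 CPM of nuclear genes against 3389, 5548 and 1518 in muscles 1 to 3. These are 5 of 63 groups of values tested, and chance gives about 1 in 20 for independent groups. The myosin shares are parts of 1 total and move together, so they are not separate outliers. The first versus last end difference of muscles 1 and 2 minus that of muscles 3 and 4 was -1.44 for Col1a1 (edgeR interaction, adjusted p = 0.0229) and -0.99 for Col1a2 (edgeR interaction, adjusted p = 0.0196). By the edgeR interaction test 8 genes passed for first versus last end (526 at unadjusted p under 0.05) and 0 for ends versus middle (460 at unadjusted p under 0.05), and no other tool was run.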

How the results depend on the processing

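The outermost sections left out, the barcode sets, thinning, saturated genes left out, entries naming several genes, uncorrected UMI numbers and the kept-section threshold were chosen after seeing the data. Of 46 named genes for ends versus middle 13, and of 58 for first versus last end 20, stayed past the threshold in the same direction in all settings that tested them, other than the all-barcode threshold, no replicate block and single barcode sets. The numbers of genes called for ends versus middle (135) were 42 with 3 zones, 333 with 10 zones, 88 with equally weighted sections in limma, 69 with the outermost sections left out, 44 and 55 within the barcode sets of muscles 1 and 2 and of muscles 3 and 4, 69 with thinned sums, and 38 to 183 with 1 muscle left out. For first versus last end (296) they were 131 with 10 zones, 167 in limma, 161 and 74 within the barcode sets, 192 thinned and 87 to 201 with 1 muscle left out. With no low-count filter 202 passed. For any zone (371) they were 244 in limma, 179 and 158 within the barcode sets, 234 thinned and 173 to 327 with 1 muscle left out. Without the replicate block that pairs the zones of a muscle, edgeR called 0, 1 and 4 genes (193, 321 and 158 at unadjusted p under 0.05), since differences between muscles then enter the spread, and all named calls were lost. Fewer genes were tested after thinning (6729), and fewer muscles entered the barcode sets; otherwise the cause was not tested. camera called 6 to 12 lists (13) at the ends with 1 muscle left out, and with an estimated correlation 2 at the ends and 4 (9) between the ends. By fry 12 lists passed at the ends and 10 between the ends. The 10 lacked the Schwann cell list (fry adjusted p = 0.113). They included the myotendinous junction (fry adjusted p = 0.0470) and satellite cell lists (fry adjusted p = 0.0364), both lower at the first end. Within single muscles, total count scaling left 26 genes (49) in all 4, and with counts as weights the distance of Col22a1 from the centre was 0.265.

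Sections chosen by a threshold over all barcodes include barcodes outside the kept tissue by construction. For ends versus middle the log2 differences then changed sign for Mss51 (-0.65), Net1 (-0.47), Tmem100 (-0.66), Ctxn3 (-1.10), Wsb2 (-4.35), Zfp943 (-0.78), Eda2r (-0.47), Serinc2 (-0.30), Casq1 (-0.79), Mybpc2 (-0.63), Myl1 (-0.66), Myl4 (-3.01), Tpi1 (-0.59), Pgm1 (-0.76) and Pkm (-0.78), and for Col15a1 (0.26), Mfap5 (0.68), Col6a2 (0.43), Dcn (0.91), Gsn (0.36), Pmp22 (0.62), Sox10 (1.42) and C1qb (0.89). For first versus last end it did so for Tmem100 (0.48), Sorbs2 (0.12), Mss51 (1.02), Mib1 (0.036), Actn3 (1.13), Myh4 (1.12) and Sox10 (-0.55). The Myh1 share became 1.14 points (ends minus middle) and -5.83 points (first minus last end), the Myh2 share -0.364 points (ends minus middle), and the Myh4 share -0.779 and 5.73 points. Cfd was at -0.021 at the ends with thinned sums and Acta2 at -0.17 between the ends with 10 zones; the cause was not tested. Leaving out mitochondrial transcripts, keeping entries that name several genes and the kept-section threshold reversed no named gene.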

Other observations

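The genes named here, out of 3538 that differed between the 2 pairs of muscles, were chosen after their values were seen, and no list was tested between the pairs. Muscles 1 and 2 had more of the metallothioneins Mt1 (3.68 log2 units) and Mt2 (4.95), of the glucocorticoid targets Fkbp5 (2.81) and Zbtb16 (2.703), of the growth regulators Ddit4 (4.07) and Cdkn1a (3.17), and of the noncoding RNA H19 (2.20). They also had more Myh2 (1.69, edgeR adjusted p = 0.0013), Myh1 (0.97, edgeR adjusted p = 0.00569) and Mss51 (1.99). Muscles 3 and 4 had more of the polyamine enzymes Smox (-4.68) and Odc1 (-3.16) and of the glycolytic enzyme Pkm (-1.93). Myh4 differed by -0.57 and did not pass (edgeR adjusted p = 0.0936). Some near-identical genes had very different counts in the pairs: Rps13 was counted 8, 8, 3153 and 2882 times in muscles 1 to 4 and Rps13-ps1 606, 512, 1 and 0 times, and Hba-a2 was counted 16319, 14704, 415 and 413 times against 23622, 21277, 21165 and 30015 for Hba-a1. The sum of such copies was not kept between the pairs and how their reads were assigned was not tested, so their differences between muscles are uncertain.

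Nnat, which encodes the membrane protein neuronatin, was singled out after its values were seen. In the 25 barcodes after the last kept section it was at 158, 1530.3, 172 and 948 CPM of nuclear genes in muscles 1 to 4, against 7.89, 13.9, 0.103 and 0.132 in the kept sections. Macrophage markers were at 83.2, 144, 391 and 108 CPM there, against 89.6, 111, 92.6 and 127 in the kept sections. The erythrocyte list stayed higher at the first end with thinned zone sums (camera adjusted p = 1.67e-14, median 1.66) and with mitochondrial and saturated genes left out (camera adjusted p = 9.71e-14, median 1.67), tests that were run after that list's difference had been seen.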
